A study of Mus musculus with 23 samples.

How the data were processed

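Brain RNA of 23 mouse libraries was profiled after preparation with a stranded mRNA library kit, per the labels' protocols. The deposited table holds a signal per gene and library, normalized counts with decimals, and not raw counts. Salmon 1.1.0, R 3.6.2, DESeq2 1.26.0 and the build GRCm38 are named per the submitters' processing notes, which give no roles or order. The filter that left 18578 genes is not given in the sources used here. The lowest mean of a gene in the table was 3.08. Whole reads could not be recovered from the deposited values, since between 17.3% and 49.1% of the low values of a library lay within 0.1 of a whole multiple of its step. Sequencing depth is therefore unknown, no counting error was computed, and no count model was fitted. The design fixed in advance had named a count test first, with limma for the case that the table held normalized values, and limma was used. One library column of the table, 1 of 24, matched no sample in the labels and was not used.

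Groups came from the titles: HT control, HT shock, WT control and WT shock, with 6, 6, 6 and 5 libraries. HT stands for the genotype that the labels call heterotype and the series text heterozygous. In WT shock the replicate numbers of the titles differ from those of the bracketed library names, and the title numbers are used here. Gene symbols were matched by Ensembl ID, for 18563 of 18578 IDs, with positions on GRCm38. Multi-copy genes and pseudogenes share reads with their copies, and their values are uncertain.

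Values were transformed as log2(normalized count + 1), and genes with a mean of at least 10 were kept, 17118 in all. Fold changes are on that scale, which understates the change of low genes. A limma model (limma 3.58.1, statmod 1.5.0, R 4.3.3) with the 4 groups in one fit, a mean-variance trend and robust moderation gave 5 contrasts, each adjusted by Benjamini-Hochberg over all genes tested, with an adjusted p of 0.05 as the threshold. The 30 gene lists, covering cell types, brain regions, synapses, activity, stress and energy metabolism, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Sets were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The rule named Grin2b, the 8 highest and 8 lowest fold changes among called genes with a mean of at least 20 and a symbol that is not a predicted or clone name, or where none passed the 3 smallest p in each direction, and up to 4 called members of each list or the 2 with the smallest p, and in the interaction also the genes named in the shock comparisons. Some genes that the rule selects are not reported here. A library was to be doubted where its correlation with its group was below that of every other library by more than 3 median absolute deviations, and 0 libraries met this. Among all pairs of libraries the highest correlation was 0.9908, and no pair was treated as duplicates.

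The model was tested on simulated data with 200 genes changed between HT shock and WT shock in each of 3 runs over 17118 genes. It recovered 36.7% of genes changed by 0.25 on the log2 scale, 77.3% at 0.5, 92.7% at 1 and 100% at 2, with 24 false calls among 50754 unchanged genes. Simulated genes were independent, which real genes are not.

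The alternatives fixed in advance were median centring, no filter and a stricter filter (20 in at least 5 libraries), pseudocounts of 0.5 and 5, the compared groups alone, the replicate number as a block by either numbering, library weights, the first residual component as a covariate, an adjusted p of 0.1 and the omission of each library. A correction of each library for transcript length and GC content, precision weights by vooma and 5 more region lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.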

Results

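RNA sequencing of brain tissue was reported for 23 libraries from male C57BL/6J mice of 2 genotypes, wild type (WT) and heterozygous for an edited Grin2b allele named C456Y (HT), with and without foot-shock, an aversive electrical stimulus to the paws. Grin2b encodes the GluN2B subunit of the NMDA receptor, a glutamate-gated channel of synapses. There were 6 WT control, 5 WT shock, 6 HT control and 6 HT shock libraries. The series text describes adult mice whereas the sample labels give postnatal day 17, so the age of the animals is unresolved. The brain region was not named. Values were normalized counts for 18578 genes, of which 17118 with a mean of at least 10 were tested. Totals per library lay between 30.98 M and 32.57 M normalized counts (M, mega), which do not show sequencing depth, and depth is unknown. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may be technical.

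Libraries correlated closely, with a median correlation to the other libraries of the same group between 0.9856 and 0.99 on the log2 scale. The first principal component (12.9% of the variance) placed the 6 HT shock libraries between 11.4 and 26 and the 11 WT libraries between -18.5 and 1.63. Of the HT control libraries, replicates 1 to 5 lay between -12.7 and 5.17 and replicate 6 lay at 31.3, beyond every HT shock library.

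**Figure D1:**
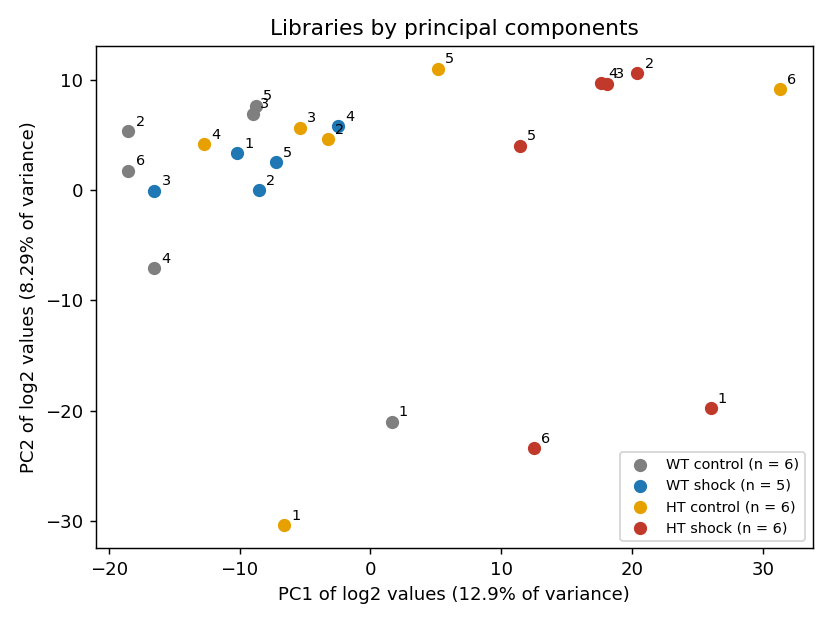
Principal components of the log2 values of 23 libraries, one point per library with its replicate number, coloured by group. On PC1 (12.9% of variance) HT shock libraries lie between 11.4 and 26, and HT control replicate 6 lies at 31.3.

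Grin2b itself (ENSMUSG00000030209, GRCm38 chromosome 6, 135713233 to 136173511, minus strand, protein coding) was expressed in every library. Mean normalized counts were 13620 ± 1020 (SD, n = 6) in WT control, 12830 ± 1390 (SD, n = 5) in WT shock, 12300 ± 1680 (SD, n = 6) in HT control and 10700 ± 655 (SD, n = 6) in HT shock. In HT shock against WT shock the log2 difference was -0.26 ± 0.08 (SE, limma adjusted p = 0.0507), and in HT control against WT control it was -0.16 ± 0.08 (adjusted p = 0.465). In HT shock against HT control Grin2b did not pass with all libraries. Without HT control replicate 6 the difference there was -0.26 ± 0.07 (adjusted p = 0.0154). An allele named for an amino acid change need not alter the mRNA level, so these values do not check the genotype labels.

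The first comparison asked what foot-shock changed in wild-type brain. No gene passed an adjusted p of 0.05 in WT shock against WT control. At an unadjusted p under 0.05 limma counted 637 genes, against 856 given by chance. The smallest p values with a higher level after shock belonged to Fam129b (log2 0.20 ± 0.05 SE), Ndrg2 (0.11 ± 0.03) and Pcdhb7 (0.35 ± 0.09), and those with a lower level to Gcc1 (-0.25 ± 0.06), Pcnt (-0.23 ± 0.07) and Ndufab1 (-0.22 ± 0.07), all with adjusted p = 0.998. No member of any of the 30 gene lists passed, adjusted over all genes or adjusted over the list alone. By camera 10 lists stood above other genes and 9 below, with vascular and ventricular markers among those above. So were oligodendrocyte (median 0.085, camera adjusted p = 6.4e-05) and astrocyte markers (0.055, camera adjusted p = 0.000158). With an estimated correlation these had adjusted p = 0.432 and 0.397. The estimated correlation was 0.496 for oligodendrocyte, 0.185 for astrocyte, 0.242 for endothelial and 0.642 for striatal genes, against the preset 0.01. For hypothalamic genes it was lower, at 0.00069. Where the estimate lies far above the preset, camera p values at the preset overstate the evidence, here and in the other comparisons. The oligodendrocyte median was 0.132 without WT shock replicate 3 and 0.042 without WT shock replicate 4. The 20 endothelial markers had a median log2 change of 0.16 with 0 members negative (camera adjusted p = 3.77e-10, adjusted p = 0.166 with an estimated correlation). Ramp2 (0.27 ± 0.09) and Ly6c1 (0.27 ± 0.10) had the smallest p among them. Markers of choroid plexus and ependyma, the cells that line the ventricles, had a median of 0.20 (camera adjusted p = 3.09e-06, adjusted p = 0.402 with an estimated correlation). Mural and fibroblast markers had a median of 0.17 (camera adjusted p = 4.22e-05, adjusted p = 0.432 with an estimated correlation). Genes of striatal projection neurons had a median of -0.09, with 18 of 19 members negative (camera adjusted p = 0.000388, adjusted p = 0.432 with an estimated correlation). Immediate early genes, which respond to neuronal activity within minutes, had a median of -0.08 (camera adjusted p = 0.0287, adjusted p = 0.681 with an estimated correlation), and without WT control replicate 5 the median was 0.003 (adjusted p = 0.857). That call was also lost without WT control replicates 2 (median -0.03) or 4 (-0.04) and without WT shock replicates 4 (-0.05) or 5 (-0.004), while the median was -0.15 without WT control replicate 3 or WT shock replicate 2. The choroid plexus median was 0.30 without WT shock replicate 2. Arc, an immediate early gene singled out after its values were seen, ranged from 2325 to 9024 normalized counts among WT control libraries and from 2248 to 5825 among WT shock libraries.

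The second comparison asked the same of heterozygous brain. No gene passed in HT shock against HT control, where limma counted 2352 genes at an unadjusted p under 0.05 and the smallest adjusted p was 0.0665. The leading higher values were those of Prrc2a (log2 0.21 ± 0.04 SE, adjusted p = 0.0665), Thy1, a neuronal surface glycoprotein (0.25 ± 0.05, adjusted p = 0.0665), and Setd2 (0.20 ± 0.04, adjusted p = 0.212). The leading lower values were those of Chd6 (-0.32 ± 0.06, adjusted p = 0.0675), Soga1 (-0.40 ± 0.08, adjusted p = 0.0759) and Fat2 (-0.30 ± 0.06, adjusted p = 0.163). Adjusted over the list alone, 14 of 19 striatal genes passed as lower, against 0 adjusted over all genes, and their median was -0.24 (camera adjusted p = 3.64e-11, adjusted p = 0.63 with an estimated correlation). Adora2a, an adenosine receptor, had -0.49 ± 0.12 and Scn4b, a sodium channel subunit, -0.37 ± 0.09. Interneuron markers had a median of 0.12, and 6 of 24 passed as higher adjusted over the list alone against 0 over all genes (camera adjusted p = 0.000711, adjusted p = 0.63 with an estimated correlation). Vip (0.27 ± 0.07) and Sst (0.26 ± 0.07), both neuropeptides of interneurons, led them. Nuclear-encoded respiratory chain genes (median 0.08, camera adjusted p = 9.38e-08) and cytosolic ribosomal protein genes (median 0.08, camera adjusted p = 2.3e-07) stood above other genes, with adjusted p = 0.899 for both with an estimated correlation. The striatal median was -0.16 without HT shock replicate 1. The respiratory chain and ribosomal medians were 0.05 each without HT control replicate 1 and 0.12 each without HT control replicate 6, and the ribosomal median was 0.05 without HT control replicate 4. Both calls were lost after correction for transcript length and GC content, with medians of 0.01 each (adjusted p = 0.407 and 0.378). Immediate early genes had a median of 0.16 with 30 of 35 members positive (camera adjusted p = 0.00474, adjusted p = 0.899 with an estimated correlation), a call lost without HT control replicates 5 or 6 (adjusted p = 0.118 at the highest), and a median of 0.24 without HT control replicate 4 or HT shock replicate 5.

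The count in this comparison changed with a single library and with the weighting of libraries. Without HT control replicate 6, 2065 genes passed, 768 higher and 1297 lower after shock. With all libraries, replicate 6 included, and weights estimated per library, 2792 genes passed, 1211 higher and 1581 lower. With all libraries, 4 genes passed with the first residual component as a covariate, 1 after correction for transcript length and GC content, 1 with only the compared groups in the fit and 4 at an adjusted p under 0.1. The counts were 1 without HT control replicate 3, 6 without HT shock replicate 6 and 4 without WT control replicate 1. With replicate 6 left out, Thy1 (log2 0.29 ± 0.04 SE, adjusted p = 0.00102), Prrc2a (0.23 ± 0.04, adjusted p = 0.00102) and Sst (0.33 ± 0.05, adjusted p = 0.0016) passed as higher. Soga1 (-0.49 ± 0.06, adjusted p = 5.24e-05), Scn4b (-0.44 ± 0.08, adjusted p = 0.00383) and Drd2, the D2 dopamine receptor (-0.36 ± 0.10, adjusted p = 0.0192), passed as lower. Grin2b passed as lower too (-0.26 ± 0.07, adjusted p = 0.0154). In that setting 10 striatal genes were lower and 0 higher, 19 ribosomal protein genes and 17 respiratory chain genes were higher and 0 lower, and 37 autism risk genes were lower and 6 higher. With all libraries the autism risk list had a median of -0.052 (camera adjusted p = 0.00769, adjusted p = 0.899 with an estimated correlation). That call was lost without HT control replicate 1 (-0.034, adjusted p = 0.203) and after correction for transcript length and GC content (-0.011, adjusted p = 0.683). No rule fixed in advance excluded HT control replicate 6.

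The third comparison asked how the genotypes differed without shock. No gene passed in HT control against WT control, while 2 passed without HT control replicate 4 and 5 passed at an adjusted p under 0.1. Limma counted 1895 genes at an unadjusted p under 0.05 and the smallest adjusted p was 0.0861. That value was shared by Fam129b (log2 0.25 ± 0.05 SE) and Ptprn (0.18 ± 0.03) with higher levels, and by the mitochondrial gene mt-Nd1 (-0.22 ± 0.04), Foxo1 (-0.28 ± 0.05) and Rab33b (-0.25 ± 0.05) with lower levels. The 15 genes encoded by the mitochondrial genome all had negative values, with a median of -0.20, and 8 passed as lower adjusted over the list alone, against 0 over all genes (camera adjusted p = 1.48e-10, adjusted p = 0.155 with an estimated correlation). By fry, which tests whether a set moves one way on balance, that list had an adjusted p of 0.00791, and it was the only list to pass there. Striatal genes had a median of -0.25, and 12 of 19 passed as lower adjusted over the list alone (camera adjusted p = 2.74e-11, adjusted p = 0.303 with an estimated correlation). Choroid plexus and ependymal markers had a median of 0.33 with 0 negative members, led by Kcne2 (0.92 ± 0.25) and Ccdc153 (0.42 ± 0.12), and 4 passed adjusted over the list alone (camera adjusted p = 3.51e-08, adjusted p = 0.303 with an estimated correlation). Mural and fibroblast markers (median 0.195 with 0 negative members, camera adjusted p = 3.11e-06) and endothelial markers (0.1, camera adjusted p = 3.81e-05) also lay above other genes. With an estimated correlation they had adjusted p = 0.304 and 0.303, and the endothelial median was 0.158 without WT control replicate 6. Microglial markers had a median of 0.23 (camera adjusted p = 4.51e-05, adjusted p = 0.589 with an estimated correlation). Autism risk (median -0.07, camera adjusted p = 5.02e-07), GABA synapse (-0.09, 3.19e-05), glucocorticoid-induced (-0.10, 0.000471) and thalamic genes (-0.08, 0.0114) lay below other genes. With an estimated correlation they had adjusted p = 0.506, 0.303, 0.592 and 0.583. Voltage-gated channel genes had a median of -0.09, with 8 of 38 lower adjusted over the list alone (camera adjusted p = 6.59e-06, adjusted p = 0.303 with an estimated correlation). Respiratory chain and ribosomal protein genes passed camera with medians of 0.05 each (camera adjusted p = 7.99e-05 and 5.75e-05, adjusted p = 0.638 for both with an estimated correlation). Without HT control replicate 6 the medians were 0.01 (adjusted p = 0.483) and 0.002 (adjusted p = 0.693), that of voltage-gated channel genes was -0.05 and that of microglial markers 0.14. Those of autism risk and GABA synapse genes were then -0.031 and -0.043. The glucocorticoid call was lost without WT control replicate 6 (median -0.054, camera adjusted p = 0.112). The thalamic call was lost with library weights (median -0.052, camera adjusted p = 0.176). The ribosomal median was 0.03 without HT control replicate 5 and 0.02 without WT control replicate 4, and the respiratory chain median was 0.08 without HT control replicate 1. Both calls were also lost with library weights (adjusted p = 0.252 for respiratory chain and 0.466 for ribosomal genes) and after correction for transcript length and GC content (adjusted p = 0.146 and 0.278).

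The fourth comparison set the genotypes against each other after shock, and here 1589 of 17118 genes passed, 676 higher and 913 lower in HT shock than in WT shock. Changes were small, with a median size of 0.24 on the log2 scale, and 89 of the genes differed by over 1.5-fold. The gene with the lowest fold change was Slc6a3 (ENSMUSG00000021609, chromosome 13, 73536747 to 73578672), the dopamine transporter of midbrain neurons, at -1.77 ± 0.37 (SE, adjusted p = 0.0115). It had 149 ± 82.8 normalized counts (SD, n = 6) in HT shock and 459 ± 108 (SD, n = 5) in WT shock, against 330 ± 157 (SD, n = 6) in HT control and 373 ± 106 (SD, n = 6) in WT control. Its interaction of genotype and shock was -1.51 ± 0.52 (limma adjusted p = 0.711). Kcng3 (-1.31), Pax5 (-1.26), Fyb (-1.09), Glra1, a glycine receptor subunit (-1.04), Ptpn7 (-0.95) and Chrna6, a nicotinic receptor subunit (-0.89), were also among the lowest. The highest changes were those of Lefty2 (1.29 ± 0.30, adjusted p = 0.0153) and Cort, the neuropeptide cortistatin (0.89 ± 0.14, adjusted p = 0.00337), followed by Mcm10 (0.84), Mylk3 (0.69), Tcap (0.64), Mcmdc2 (0.62), Tcte1 (0.60) and Dkkl1 (0.58). Lefty2, Mcm10, Kcng3 and Ptpn7 had means under 33 normalized counts, where the added pseudocount shrinks fold changes.

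Striatal genes were lower in HT shock than in WT shock. Of 19 measured, 12 fell and 0 rose, and 16 were lower adjusted over the list alone. The median was -0.38 (camera adjusted p = 3.47e-12, adjusted p = 0.566 with an estimated correlation, fry adjusted p = 0.00683). Drd2 (-0.56 ± 0.10 SE), Scn4b (-0.54 ± 0.09), Adcy5, an adenylyl cyclase (-0.33 ± 0.06), and Rasd2 (-0.31 ± 0.05) were among them. By fry, 3 of 30 lists passed in this comparison, the striatal, astrocyte and interneuron lists. Lists that passed camera but not fry included glucocorticoid-induced (fry adjusted p = 0.0809), respiratory chain (0.0845), autism risk (0.119) and immediate early genes (0.172). The mean striatal score, the average log2 deviation of the list, was -0.258 ± 0.222 (SD, n = 6) in HT shock, -0.032 ± 0.118 (SD, n = 6) in HT control, 0.108 ± 0.034 (SD, n = 5) in WT shock and 0.2 ± 0.071 (SD, n = 6) in WT control. Thalamic genes also had a lower median (-0.12), with 4 of 16 lower and 0 higher, among them Tcf7l2 (-0.35 ± 0.09) and Slc17a6, a vesicular glutamate transporter (-0.33 ± 0.08), with camera adjusted p = 0.00442 and adjusted p = 0.602 with an estimated correlation.

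Markers of oligodendrocytes and astrocytes had lower medians too. Of 24 genes of mature oligodendrocytes 9 fell and 0 rose, with a median of -0.20 (camera adjusted p = 6.28e-06, adjusted p = 0.602 with an estimated correlation, fry adjusted p = 0.0747). They included the myelin genes Mobp (-0.33 ± 0.06) and Mbp (-0.28 ± 0.06). Oligodendrocyte scores of single libraries overlapped between the groups, from -0.272 to 0.077 in HT shock and from -0.05 to 0.247 in WT shock. Of 20 astrocyte markers 3 fell, namely Slc4a4 (-0.42 ± 0.08), the glutamate transporter Slc1a2 (-0.29 ± 0.06) and Acsbg1 (-0.11 ± 0.03), and 11 were lower adjusted over the list alone (camera adjusted p = 6.87e-05, adjusted p = 0.566 with an estimated correlation, fry adjusted p = 0.00683). Glucocorticoid-induced genes had a median of -0.22 with 5 of 30 lower, led by Hif3a (-0.64 ± 0.17) and Pdk4 (-0.44 ± 0.12), with camera adjusted p = 6.26e-06 and adjusted p = 0.602 with an estimated correlation. Without WT shock replicate 3, whose score for this list was 0.693 against -0.109 to 0.278 in the other WT shock libraries, the glucocorticoid median was -0.14 (adjusted p = 0.002). Microglial markers had a median of 0.10, with 1 of 22 higher and 0 lower, and did not pass as a set (camera adjusted p = 0.239). Endothelial markers, with 1 of 20 higher and 0 lower, did not pass as a set (median -0.16, camera adjusted p = 0.0684).

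Neuronal groups did not move together, with some lists higher and others lower. Of 24 interneuron markers 5 rose and 2 fell, and the risers included the neuropeptides Cort (0.89 ± 0.14), Npy (0.46 ± 0.08), Sst (0.42 ± 0.07) and Cck (0.36 ± 0.06), with camera adjusted p = 0.00403, adjusted p = 0.595 with an estimated correlation and fry adjusted p = 0.00906. Of 20 excitatory neuron markers 6 rose and 3 fell, among the risers Neurod6 (0.33 ± 0.05) and Slc17a7, the main cortical vesicular glutamate transporter (0.25 ± 0.05), with camera adjusted p = 0.0196 and adjusted p = 0.602 with an estimated correlation. That list's call was lost without WT shock replicate 5 (adjusted p = 0.0856) and with only the compared groups in the fit (adjusted p = 0.13). Of 25 GABA synapse genes 5 fell and 0 rose, among them Abat, which breaks down GABA (-0.23), the GABA transporter Slc6a11 (-0.31) and Gad2, a GABA synthesis enzyme (-0.20). Their median was -0.05 (camera adjusted p = 0.02, adjusted p = 0.603 with an estimated correlation), or -0.08 without WT shock replicate 5, and the call was lost without WT shock replicate 2 (adjusted p = 0.0549). Immediate early genes had a median of 0.28, although 1 of 35 passed, Ier5 (0.45 ± 0.09), with camera adjusted p = 0.000143 and adjusted p = 0.604 with an estimated correlation. Nuclear respiratory chain genes had a median of 0.11 with 9 of 79 higher and 0 lower (camera adjusted p = 5.86e-10, adjusted p = 0.602 with an estimated correlation), while of 15 mitochondrially encoded genes 6 fell and 0 rose, such as mt-Nd5 (-0.37 ± 0.08) and mt-Co1 (-0.22 ± 0.05), with camera adjusted p = 0.0129 and adjusted p = 0.602 with an estimated correlation. Of 129 autism risk genes 23 fell and 4 rose (camera adjusted p = 0.000109, adjusted p = 0.603 with an estimated correlation), and of 38 voltage-gated channel genes 10 fell and 2 rose (camera adjusted p = 0.00235, adjusted p = 0.602 with an estimated correlation). After correction for transcript length and GC content the calls of the respiratory chain (median 0.02, adjusted p = 0.0775), autism risk (-0.02, adjusted p = 0.215), voltage-gated channel (adjusted p = 0.0659) and GABA synapse lists (0.005, adjusted p = 0.467) were lost. In NMDA receptor and postsynaptic scaffold genes 3 of 34 rose and 2 fell, and the set did not move one way (camera adjusted p = 0.838). Adjusted over the list alone, 3 were higher and 4 lower. Fry for changes in either direction gave this list an adjusted p of 0.00476. That was not particular to it, as presynaptic genes had 2.86e-05 and AMPA, kainate and metabotropic glutamate receptor genes 0.000155 by the same test.

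**Figure D2:**
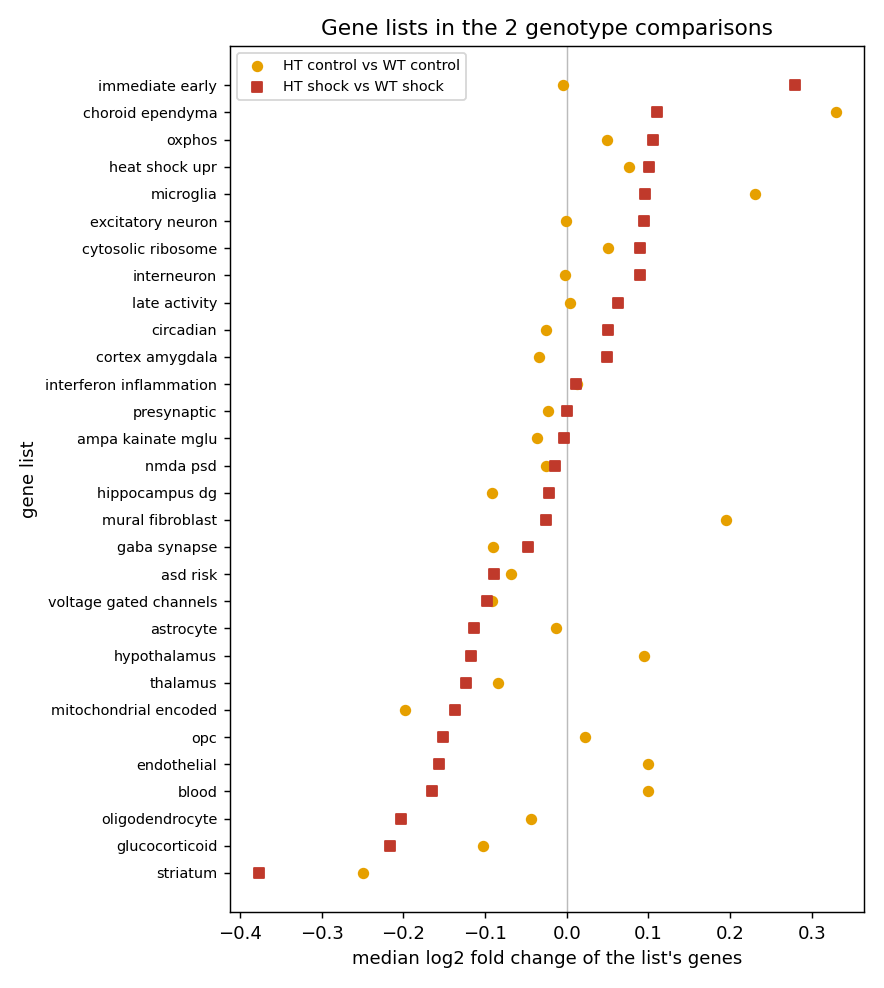
Median log2 fold change of the measured genes of 30 lists (rows) in HT control against WT control (circles) and HT shock against WT shock (squares). Striatal genes have the lowest median in both comparisons, -0.25 and -0.38.

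**Figure D3:**
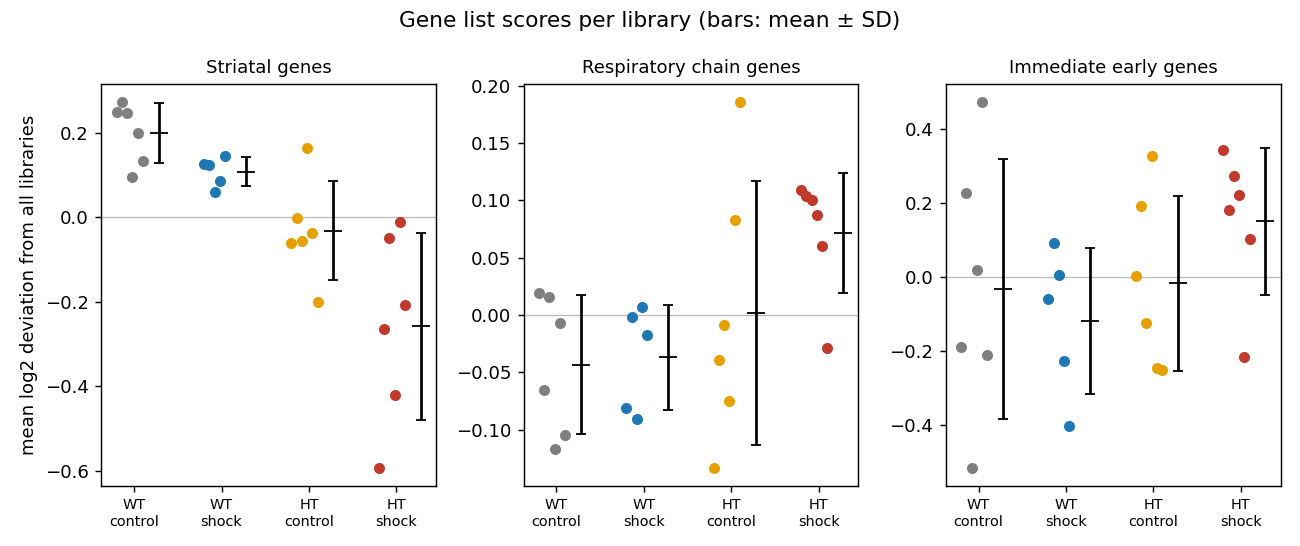
Scores of 3 lists per library, as the mean log2 deviation of the list's genes from their mean over all libraries. Points are libraries, bars the group mean ± SD (n = 5 or 6). Striatal scores in HT shock average -0.258 and in WT shock 0.108.

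The count of 1589 depended on single libraries. It was 422, 497, 577 and 839 without HT shock replicates 1, 2, 3 and 4, 756, 611, 723 and 851 without WT shock replicates 1, 2, 3 and 5, and 2923 without HT control replicate 6, which enters through the shared estimate of spread. It was 2932 with only the compared groups in the fit, 3775 with library weights, 3092 at an adjusted p under 0.1 and 951 after correction for transcript length and GC content. Of the 97 genes selected by rule and called in this comparison, 34 lost their call after that correction, and 45 passed under each of the 23 omissions, including Slc6a3, Pax5, Chrna6, Cort, Npy, Sst, Drd2, Adcy5, Mbp, Slc1a2 and Neurod6. Calls were lost without single shocked libraries for Acsbg1 (in 9 omissions), Mcmdc2, Tcte1 and Gad2 (8 each), Mcm10, Mylk3 and Hif3a (7 each), Pdk4 (6), Ptpn7 and Tcf7l2 (5 each), Kcng3 and Tcap (4 each) and Slc17a6 (2). Glra1 lost its call in 16 omissions, control libraries among them. The highest adjusted p that any of these genes reached was 0.125, for Tcte1.

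**Figure D4:**
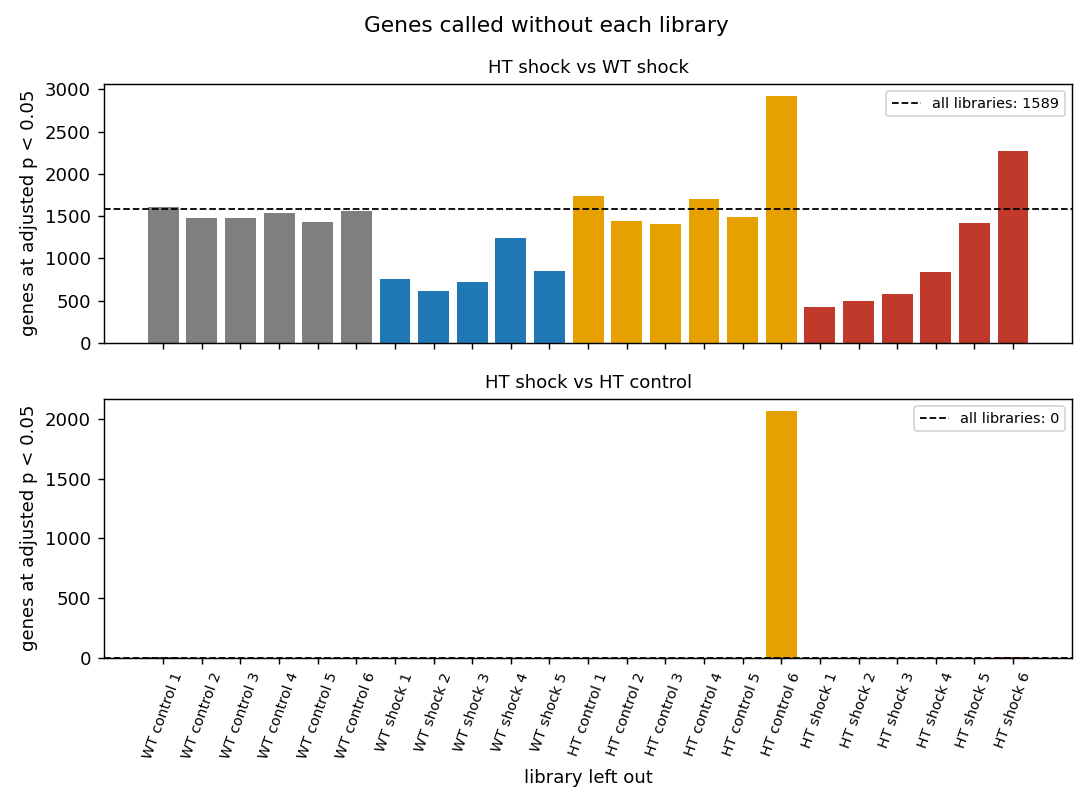
Genes at an adjusted p under 0.05 (bars, from 0) after each library in turn was left out, with the count for all libraries as a dashed line. HT shock against WT shock ranges from 422 to 2923, and HT shock against HT control reaches 2065 without HT control replicate 6.

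The last comparison asked whether shock acted differently in the genotypes. No gene passed the interaction test, with 1101 genes at an unadjusted p under 0.05 in limma and a smallest adjusted p of 0.552. The leading genes were Rspo1 (0.67 ± 0.15 SE), Creb3 (0.41 ± 0.09) and Pcnt (0.40 ± 0.09) on the positive side and Chd6 (-0.42 ± 0.09), Cpne1 (-0.38 ± 0.08) and Pcdhb7 (-0.52 ± 0.12) on the negative side. Thus the 1589 genes that differed between genotypes after shock and the 0 that differed before it were not shown to differ in their response. Of these genes, 1455 (91.6%) had the same sign in the unshocked genotype comparison, which shares no libraries with it, with a median ratio of 0.406 between the fold changes. Selection for passing after shock tends to enlarge the fold changes there, which lowers this ratio. Over all genes tested the share with the same sign was 69.2%, and over the higher-expressed genes 77.6%. Across all genes the fold changes of the genotype comparisons correlated at r = 0.288, and across the 8559 genes above the median level at r = 0.639. The shock responses of WT and HT correlated at r = -0.002 across all genes and 0.088 across the higher-expressed genes. By rank (Spearman) the values were 0.085 and 0.215, against 0.43 and 0.691 for the genotype comparisons. The shock responses had the same sign in 55.2% and 58.7% of genes. In WT, 637 genes had an unadjusted limma p under 0.05, against 856 given by chance. An r near 0 therefore does not show that the responses differ. Genes are not independent replicates, and these correlations are descriptive. The sign shares and the correlations of the genotype comparisons were not computed without HT control replicate 6, which enters the unshocked one. By camera, 5 lists lay above and 8 below other genes in the interaction. Endothelial markers had a median of -0.29 (camera adjusted p = 1.97e-07, adjusted p = 0.168 with an estimated correlation), astrocyte markers -0.12 (camera adjusted p = 2.54e-06, adjusted p = 0.168 with an estimated correlation), immediate early genes 0.23 (camera adjusted p = 9.53e-05, adjusted p = 0.626 with an estimated correlation) and interneuron markers 0.15 (camera adjusted p = 0.000117, adjusted p = 0.168 with an estimated correlation). The interaction test passed 1 gene without HT control replicate 6, 2 with library weights and 1 after correction for transcript length and GC content. No list passed with an estimated correlation in any of the 5 comparisons. By fry, 0 lists passed in the interaction and in either comparison of shock with control.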

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

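The test of a wrong label on HT control replicate 6 was chosen only after the result was seen, and so were the count of original calls kept and the striatal median in the tests of transcript length and GC content, and the reading of the tests of regional make-up.

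Single libraries stood apart from the rest of their group in 15 of 272 groups of values tested, where chance, at about 1 in 20, gives about 14. HT control replicate 6 was apart in 3 of them, with a score of -0.192 for GABA synapse genes (others -0.023 to 0.061), -0.231 for thalamic genes (others -0.022 to 0.096) and a total of 30.98 M normalized counts (others 31.76 M to 32.08 M). HT shock replicate 6 was apart in autism risk genes at -0.01 (others -0.081 to -0.064) and respiratory chain genes at -0.029 (others 0.06 to 0.109). HT shock replicate 5 was apart in excitatory neuron markers at -0.072 (others 0.028 to 0.083) and cortical and amygdala genes at -0.052 (others -0.006 to 0.018). WT control replicate 2 was apart in oligodendrocyte genes at -0.146 (others 0.008 to 0.081) and in Chrna6 at 87.8 normalized counts (others 61.94 to 69.38). HT control replicate 4 had a blood gene score of -0.575 (others -0.014 to 0.293), and HT control replicate 5 had 178.1 normalized counts of Pcdhb7 (others 214.7 to 236.3). In WT shock, replicate 1 had 157.8 of Pax5 (others 36.79 to 61.83), replicate 2 had 31.51 of Lefty2 (others 10.61 to 13.05) and 1073 of Creb3 (others 846.2 to 895.9), and replicate 4 had 1190 of Fam129b (others 1082 to 1107).

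The shock response of 13 gene lists differed between genotypes by camera on the interaction, and none of the 13 passed with an estimated correlation. Median differences of the response, HT minus WT, were 0.227 for immediate early genes, 0.15 for interneuron markers, 0.087 for excitatory neuron markers, 0.065 for respiratory chain genes and 0.035 for ribosomal protein genes. They were -0.127 for glucocorticoid-induced genes, -0.116 for astrocyte, -0.17 for oligodendrocyte, -0.154 for oligodendrocyte precursor, -0.288 for endothelial, -0.225 for mural and fibroblast and -0.229 for choroid plexus and ependymal markers, and -0.152 for striatal genes. Without HT control replicate 6 the excitatory neuron, oligodendrocyte precursor and choroid plexus lists no longer passed, nor did the glucocorticoid list, and ribosomal protein genes lost the call in 10 of 23 omissions. The highest adjusted p over the omissions was 0.0629 for the excitatory neuron and oligodendrocyte precursor lists, 0.0956 for choroid plexus, 0.386 for ribosomal protein and 0.595 for glucocorticoid-induced genes (without WT shock replicate 3, median -0.041). The choroid plexus median was -0.124 without HT control replicate 6, -0.152, -0.36 and -0.131 without WT shock replicates 1, 2 and 5. The respiratory chain median was 0.039 and 0.104 without HT control replicates 1 and 6, 0.041 without WT shock replicate 1, and 0.016 after correction for transcript length and GC content (adjusted p = 0.45). The ribosomal median was 0.007, 0.059 and 0.087 without HT control replicates 1, 5 and 6, 0.063 without HT shock replicate 6 and 0.058 without WT control replicate 4.

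An arbitrary grouping of the 11 shocked libraries was argued against, though not excluded, as the source of the difference between HT shock and WT shock. Of 100 splits drawn from those possible, 1 gave as many genes, the real one with 1589. The highest of the others gave 639, so a split that mixes the genotypes can also give many genes. A different regional make-up of the sampled tissue may contribute: the fold changes outside the striatal list were then to correlate at -0.3 or below with each gene's slope on the striatal score among the 6 WT control libraries, and r was 0.099, where permuted scores (720 exact permutations) gave only -0.229 to 0.22. Among higher-expressed genes, where permuted scores reached -0.556 to 0.556, r was 0.469, opposite in sign to the prediction but above -0.1 by less than 2 SD of the permuted values (SD 0.302), so this stays open. A bias of transcript length or GC content as the cause of the lower striatal genes was argued against, since after correction their median was -0.411 (-0.377 before, and -0.475 to -0.344 over 11 omissions of 1 shocked library) with 13 lower against 12 before. For the 1589 genes as a whole it stays open, since 951 passed after correction but 708 (44.6%) of the original genes kept their call and direction, between the bounds set for and against it, and the effect of genotype itself stays open too.

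HT control replicate 6 lay beyond the HT shock libraries on the first principal component, and a wrong treatment label is a candidate explanation. On an axis from the other HT control libraries (0) to HT shock (1), it lay at 1.408. The shocked libraries, each placed without itself, spanned 0.397 to 1.106, and a shocked library was predicted to lie inside that range. The other HT control libraries spanned -0.114 to 0.641, which overlaps it, so a place inside the range would not mark a shocked library. The label of replicate 6 therefore cannot be told apart from other reasons for an extreme library. A regional difference stays open, as its striatal score of -0.201 was the lowest of its group, and the test (r = 0.066 against the same slopes, -0.3 or below predicted) could not reach its bound where permuted scores gave only -0.139 to 0.131. Among higher-expressed genes r was 0.537 (permuted -0.656 to 0.676, SD 0.36), opposite in sign to the prediction but above -0.1 by less than 2 SD. A biological difference of that sample was not tested, nor was a technical one such as a transcript length or GC bias. Of all libraries, replicate 6 had the highest ribosomal protein (0.224) and respiratory chain (0.186) scores. Its autism risk (-0.192) and voltage-gated channel (-0.205) scores were the lowest.

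DNA carried along with the edited allele could place genotype differences near Grin2b. Within 10 Mb, 7 of 109 genes were among the 1589, 6.42% (95% exact interval 2.62 to 12.8), against 9.3% elsewhere (one-sided Fisher exact p = 0.89). No excess was found, and the interval leaves a small one open.

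For the comparisons with 0 called genes by limma, splits of the libraries say nothing about chance, since each of the 100 must give at least 0 genes. The highest other split gave 1 in WT shock against WT control, 1 in HT shock against HT control, 17 in HT control against WT control and 18 in the interaction.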

How the results depend on the processing

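The corrections for transcript length and GC content and the vooma weights were chosen after seeing the data. The count of 0 in WT shock against WT control was the same under every alternative run. In HT shock against WT shock the count was 450 with the replicate block by title number and 976 with the replicate block by bracketed number, 3775 with library weights, 951 after the length and GC correction, 2932 with the compared groups alone and 3092 at an adjusted p under 0.1, and from 422 to 2923 over the omissions of 1 library. In HT shock against HT control it was 2792 with library weights, 4 with the residual component, 1 after the length and GC correction, 1 with the compared groups alone and 4 at an adjusted p under 0.1, and from 0 to 2065 over the omissions. In HT control against WT control it was 5 at an adjusted p under 0.1 and from 0 to 2 over the omissions, the 2 without HT control replicate 4. The interaction gave 2 with library weights, 1 after the length and GC correction and from 0 to 1 over the omissions. Median centring, both filters, both pseudocounts and vooma moved no count by over 1.5 times. The correlation of the shock responses (r = -0.002, jackknife SE 0.089) lay between -0.028 and 0.048 over the omissions, and was 0.088 among higher-expressed genes, just over 1 SE away. The cause of these changes was not tested, except that weaker thresholds admit more genes and omissions leave fewer libraries.

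The labels do not say that equal replicate numbers mark pairs, and the correlations did not show pairs throughout. Those of same-numbered libraries lay between -0.154 and 0.194, and in no pair of groups were all over 0.1. By title number, 4 of 5 HT shock libraries correlated best with the WT shock library of their own number. The mean r was 0.077 there, against -0.015 for other pairs of these groups. This is a hint of pairing from the data and not the design, and it leaves pairing in that comparison open. With the block, the counts of 0 stayed at 0. Of the 97 named genes called in HT shock against WT shock, 42 lost their call with the block by title number and 22 by bracketed number.

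No call of a named gene changed direction. Over the omissions, 8090 results of named genes were the same, 58 were stronger and 362 weaker, and for lists 1560 were the same and 117 weaker. Of lists, 5 medians or directions reversed. After the length and GC correction the median of ribosomal protein genes was -0.003 in the interaction and -0.004 in HT shock against WT shock, and that of GABA synapse genes there was 0.005. In WT shock against WT control late activity genes had 0.005 without WT shock replicate 5 (-0.076 at the lowest, without WT shock replicate 3) and immediate early genes 0.003 without WT control replicate 5 (-0.152 at the lowest, without WT control replicate 3). Tests on counts were not run because whole reads could not be recovered. Unknown depth leaves the precision of low values unmeasured.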

Other observations

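The region lists in the next paragraph were chosen after the genes called in HT shock against WT shock had been seen, and are reported as values with no explanation.

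Genes of midbrain dopamine neurons were lower in HT shock than in WT shock. Of 12 measured, 6 fell and 0 rose, with a median of -0.39 (camera adjusted p = 6.57e-06, adjusted p = 0.119 with an estimated correlation). Over the 10 members not seen before the list was made, the median was -0.334 (camera adjusted p = 0.000541). Besides Slc6a3 and Chrna6, the vesicular monoamine transporter Slc18a2 (-0.58 ± 0.16 SE), the synthesis enzyme Ddc (-0.42 ± 0.11), the receptor Ret (-0.41 ± 0.11) and Aldh1a1 (-0.28 ± 0.04) fell, while Th, the rate-limiting enzyme of dopamine synthesis, had -0.18 ± 0.10 (adjusted p = 0.238). These p values are not independent of the choice of the list, which followed from called genes. Cerebellar genes had a median of -0.14, with 3 of 16 lower, among them Fat2 (-0.30 ± 0.07) and Rgs8 (-0.16 ± 0.05), and camera adjusted p = 0.0101 (adjusted p = 0.368 with an estimated correlation). Serotonin neuron (median -0.14, camera adjusted p = 0.0681) and olfactory bulb genes (median 0.15, camera adjusted p = 0.0797) did not pass as sets, nor did hindbrain genes (camera adjusted p = 0.15), whose median turned from -0.13 to 0.03 without members seen before the list was made. In HT control against WT control none of the 5 lists passed, and the midbrain list had a median of -0.08 (camera adjusted p = 0.802). Its interaction of genotype and shock had a median of -0.29 (camera adjusted p = 1.83e-07, adjusted p = 0.0576 with an estimated correlation), with medians of 0.11 in WT shock against WT control (camera adjusted p = 0.0153, adjusted p = 0.746 with an estimated correlation) and -0.20 in HT shock against HT control (camera adjusted p = 1.73e-05, adjusted p = 0.0854 with an estimated correlation). Without the midbrain members seen before the list was made, the WT call was lost (median 0.089, camera adjusted p = 0.0763). The interaction median was then -0.235 (camera adjusted p = 2.5e-05) and the HT median -0.157 (camera adjusted p = 0.000981). Cerebellar genes had an interaction median of -0.18 (camera adjusted p = 1.52e-06, adjusted p = 0.102 with an estimated correlation), with 0.003 in WT (camera adjusted p = 0.674) and -0.15 in HT (camera adjusted p = 3.6e-07, adjusted p = 0.0854 with an estimated correlation).

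Lcn2, an acute-phase gene named here after its values were seen, reached 820.7 normalized counts in WT control replicate 6 and 1115 in WT shock replicate 3, against 1.167 to 61.36 in the other WT control libraries and at most 30.66 in any HT library. WT shock replicate 1 had 146.1. The glucocorticoid-induced list, which holds Lcn2, passed in WT shock against WT control with a median of 0.113 (camera adjusted p = 0.000388, adjusted p = 0.432 with an estimated correlation). Without WT shock replicate 3 that list no longer passed there (camera adjusted p = 0.502).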
